A study of Drosophila melanogaster with 3 samples.

How the data were processed

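Chromatin immunoprecipitation and sequencing was done on whole white prepupae of mixed sex that expressed vri fused to GFP at its C terminus, with an antibody against GFP, in 3 biological replicates of 1 group. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The depositors' note files state that the replicate lists and the pooled list are peaks and background used as input for the irreproducible discovery rate, that each list comes from the alignments of its replicate, or of all replicates for the pooled list, together with 1 further file that is also a source of the control-normalised signal, and that the optimal list was made from the replicate and pooled lists. The aligner, the peak caller and the IDR threshold are not given in the sources used here.

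Each deposited list is in narrowPeak format. Its signal column, the authors' signal value of each peak, is not scaled between libraries. It was mainly used to rank entries within a list, or after division by the list's own median at optimal peaks. Undivided signal within the pooled list gave the medians of peaks with and without a motif and the sums around genes. The undivided medians of the replicates are given as description only. The deposited column of −log10 q values was read for its range only and entered no test. Replicate and pooled lists each hold 30000 entries, and the optimal lists hold 9264 peaks in dm6 and 9083 in dm3. All 9264 optimal peaks of dm6 are the entries of highest signal in the pooled list. Because the lists hold no read counts, the depth per library is unknown and no counting interval was given for signal. Intervals on shares of peaks and genes are exact binomial 95% intervals and treat peaks as independent, which neighbouring peaks are not.

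Coordinates are dm6, 1-based. Start sites, exons and introns came from the Ensembl annotation of the same assembly and bases from the RefSeq assembly. Of 13944 protein-coding symbols in both annotations, 13943 had identical coordinates, and 0 entries ended beyond an arm. Only the 6 arms 2L, 2R, 3L, 3R, 4 and X were used. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

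Replicate agreement was the share of optimal peaks that overlap, by at least 1 bp, one of the 9264 highest entries of a replicate, with chance from 100 circular shifts of the peaks along each arm. Positions were compared with 1000 such shifts. A gene was called bound when an optimal summit lay within 1 kb of one of its 19607 protein-coding start sites in total over 13945 genes. Motifs on either strand were searched in the 101 bp around each summit and in windows of the same size 400 bp to each side, and tested by an exact McNemar test against 1 flank drawn per peak. Words of 8 bases present in at least 20 windows of either kind were tested by Fisher's exact test, and signal ranks by a permutation test with 100000 resamples. The 27 gene lists were compared with all other genes by Fisher's exact test with Benjamini-Hochberg adjustment; list members with no gene of that symbol in the annotation were left out, for example 4 of 36 in the ecdysone list. There is 1 group, so no test between groups was made. All p-values measure peaks or genes within this one group, not differences between animals.

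Lists, motifs, tests and alternatives were set before the data were examined. The genes named were the genes of the 15 highest optimal peaks, all members of the clock list, the 12 ecdysone members with the highest peaks together with the unbound ones, and the 4 members with the highest peaks of every other list past an adjusted p of 0.05. vri was given in every replicate. A gene's value is the relative signal of its highest peak within 1 kb of a start site, averaged over the replicates in which an overlapping entry was found.

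Each test was checked on simulated data. For VP boxes planted at 3% of 9000 random summits, the measured excess over flanks was 3.01 points, and 2 of 100 draws without planting gave p under 0.05. For the word test on the same peaks, the planted word came first of 29082, 18 other words passed, and 0 words passed without planting. Those summits were placed at random along the arms, whereas 49.1% of the optimal summits lay within 1 kb of a start site. The motif and word draws therefore do not measure calls from sequence that differs between promoters and their flanks. For the gene lists, with the ecdysone list raised to near its observed share, 87 of 100 draws over 13945 genes recovered it, and 4 of 100 draws with nothing raised called any list. Each gene was drawn independently, whatever its length, start sites or neighbours. These draws therefore do not measure false calls from shared summits, gene length or clustered genes. For the signal rank test over 9000 peaks, 81 of 100 draws recovered a shift of 6% of the list and 4 of 100 without a shift gave p under 0.05. For start sites, 3 of 20 draws of 3000 random summits gave p under 0.05, so a larger set was added: 24 of 400 draws (6%, exact 95% interval 3.88 to 8.80%) did so. With 20% of 3000 summits placed on a start site the measured ratio was 1.75. For replicate agreement, 80.3% of 9000 simulated peaks were kept and 81.3% were matched.

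Alternatives covered the dm3 lists, the overlap rule, list length, windows, flanks, motif patterns, word length, gene bodies, a logistic model with gene length and number of start sites, circular shifts for the gene lists, the stronger 50% of the peaks, peaks found in all replicates, and leaving out each replicate in turn. For peak numbers, positions, motifs, words, signal ranks and gene lists, the last of these kept the optimal peaks found in the other replicates' highest entries. Their pooled signal still came from all replicates. The shift test of a gene list was planned without a statistic. The log odds ratio and the difference in bound share were both computed, and the log odds ratio was kept as the stricter after both results had been seen. Its value is the observed odds ratio divided by the geometric mean of those of the shifted peaks, which bind fewer genes.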

Results

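Binding of Vrille, a bZIP repressor of the Drosophila circadian clock that is also induced by ecdysone, was mapped by chromatin immunoprecipitation and sequencing in whole white prepupae, the stage at which the larva has just stopped moving and begun metamorphosis. The flies carried vri with GFP fused to its C terminus, and chromatin was pulled down with an antibody against GFP. There were 3 biological replicates of pooled males and females in 1 group, so the question the design asks is where the tagged protein sits and how well the replicates repeat each other. No untreated or mock library was analysed here. The values are the peak lists of the authors, in dm6 coordinates: 30000 entries for each replicate, 30000 for the pooled reads, and 9264 that passed the authors' threshold on the irreproducible discovery rate (IDR), called optimal peaks below. The read depth behind each list is unknown, because the lists hold no read counts. Signal was therefore divided, within each replicate, by that replicate's median over the optimal peaks, and this relative signal is given as mean ± SD with n = 3 (1 is the median optimal peak). The 9264 peaks had a median width of 440 bp and covered 2.41% of the 6 chromosome arms. Their density was 65.0 per Mb on X, between 68.1 and 73.1 per Mb on the arms of chromosomes 2 and 3, and 14.8 per Mb on chromosome 4.

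The highest peak of the genome had its summit 225 bp upstream of a start site of Pdp1, the PAR-domain bZIP activator that acts with Vrille in the clock (chromosome 3L, 7867014 to 7867965, with the summit outside the gene). Its relative signal was 20.7 ± 1.83 (n = 3). The peaks ranked 2 and 4 both lay in introns of vri itself on 2L. The first of them, at 5306197 to 5307544, had a relative signal of 18.3 ± 1.80 (n = 3). The other, at 5304896 to 5306255 with its summit 164 bp from an annotated start site, had 15.1 ± 0.456 (n = 3). vri held peaks ranked 3 and 5 in replicate 1, 2 and 5 in replicate 2, and 3 and 4 in replicate 3. The third peak lay in an intron of ush, which encodes a cofactor of GATA factors, 1368 bp from the start of the zinc-finger gene cbt (2L, 480543 to 481758), and had 17.6 ± 0.957 (n = 3). The other peaks among the 15 highest had relative signals between 11.2 and 15.3. They lay within 1 kb of start sites of CG12054, larp (a La-related RNA-binding protein), Mpcp2 (a mitochondrial phosphate carrier), CG14100, Ugalt and eIF2Bbeta (a UDP-galactose transporter and a translation initiation factor subunit), Gprk2 and PNPase, Lk6 (a kinase of eIF4E), CG9331 and CG1888. Of the remaining pair, one was in an intron of CG11050 and one was 5134 bp from CG1888. Of these 15 summits, 11 lay within 1 kb of a protein-coding start site.

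Of the 20 genes of the circadian clock list, 10 had an optimal summit within 1 kb of a start site, and such genes are called bound below. Besides Pdp1 and vri these were slmb, encoding an F-box protein that targets Period (relative signal 9.20 ± 1.06, n = 3), the kinase gene sgg (3.33 ± 0.225, n = 3), kay, which encodes Fos (2.37 ± 0.408, n = 3), and the phosphatase subunit gene tws (1.77 ± 0.119, n = 3). The repressor gene cwo had 1.38 ± 0.525 (n = 3). The other bound genes had weaker peaks: cry, the blue-light photoreceptor gene, had 0.661 ± 0.401, Clk, which encodes the activator that Vrille represses, had 0.627 ± 0.140, and the kinase subunit gene CkIIbeta had 0.599 ± 0.319 (n = 3 each). No summit lay within 1 kb of a start site of per, tim, cyc, CkIIalpha, Pdf, Pdfr, dco, jet, nmo or to, although nmo and dco held a peak in the gene body at ranks 1396 and 2999. The bound share of 50% was above the 27.4% of other genes by Fisher's exact test without correction (odds ratio 2.65, two-sided p = 0.0405), but not after Benjamini-Hochberg adjustment over the 27 lists (adjusted p = 0.0782). With windows of 2 kb the adjusted p was 0.0331, and with gene length and the number of start sites in a logistic model it was 0.856, with an odds ratio of 1.10. The slmb summit is shared with CG5793.

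**Figure D1:**
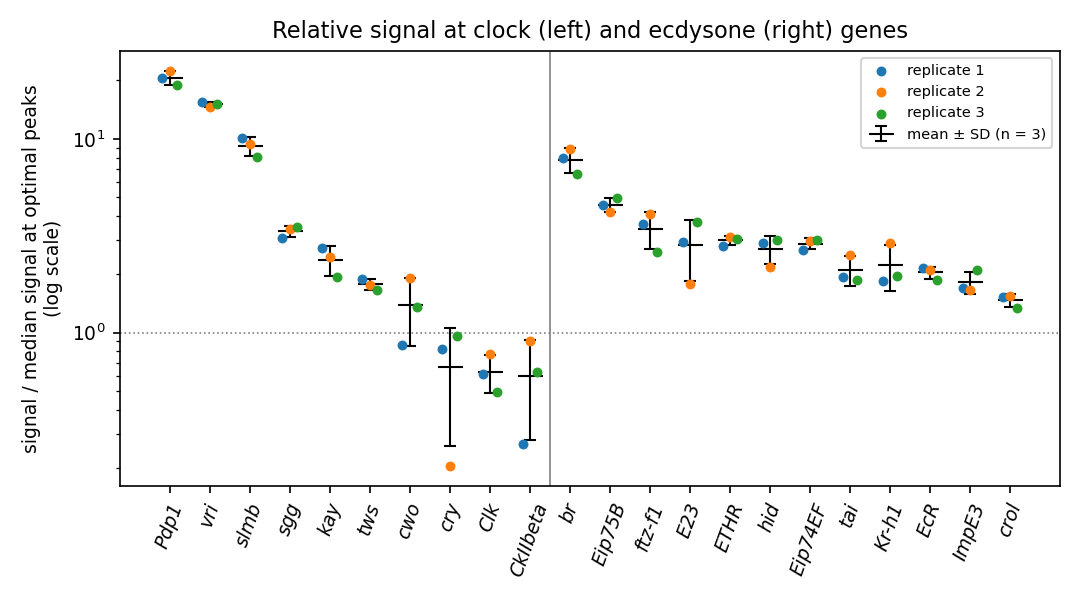
Relative signal (log scale) of the highest peak within 1 kb of a start site for the 10 bound clock genes and the 12 ecdysone genes with the highest peaks; coloured points are the 3 replicates, black bars the mean ± SD, and the dotted line the median optimal peak. Pdp1 and vri lie at 20.7 and 15.1, while cry, Clk and CkIIbeta lie under 1.

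Genes of the ecdysone response were bound more often than other genes: 22 of 32 annotated members (68.8%) against 27.4%, an odds ratio of 5.84 by Fisher's exact test (two-sided, adjusted p = 9.13e-06 over 27 lists). In the replicates' own lists of the 9264 highest entries the share was 70.8% ± 1.80 (n = 3). The strongest peak was at br, the Broad zinc-finger gene of the early puffs (X, 1609921 to 1610525, relative signal 7.78 ± 1.14, n = 3). It was followed by the nuclear receptor genes Eip75B (4.56 ± 0.375) and ftz-f1 (3.44 ± 0.744), where ftz-f1 gives prepupae their competence for the next ecdysone pulse (n = 3 each). ETHR, the receptor of ecdysis-triggering hormone, had 2.99 ± 0.170, the ETS gene Eip74EF had 2.88 ± 0.182, the ABC transporter gene E23 had 2.82 ± 0.980, and the death gene hid had 2.70 ± 0.453 (n = 3 each). Kr-h1, tai (a coactivator of the ecdysone receptor), EcR itself, ImpE3 and crol had values from 2.23 ± 0.586 down to 1.47 ± 0.113 (n = 3 each), and the ImpE3 summit was shared with CG10903 and CG2747. Members without a summit near a start site were Cyp18a1, Dronc, ETH, Eip78C, Hr39, ImpE1, ImpL1, ImpL2, Smr and mld. Among these, Eip78C and Smr held strong peaks in the gene body, at ranks 118 and 148. The odds ratio fell to 2.74 with gene length and number of start sites in a logistic model over the genes (n = 13945, adjusted p = 0.0358). When the peaks were shifted along the arms, which keeps neighbouring genes together, the observed odds ratio was 3.64 times that of shifted peaks (permutation, adjusted p = 0.0432). Neither test takes account of transcription, which was not measured here. Lists set to stand for highly transcribed genes gave 60.9% (ribosomal proteins), 56.6% (oxidative phosphorylation) and 40.7% (heat shock, not past the threshold). Those set to stand for mostly silent genes gave 2.79% (chemosensory receptors) and 6.15% (male reproductive genes). The ecdysone excess therefore cannot be told apart from signal at active promoters.

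Across the genome, 3830 of 13945 protein-coding genes were bound (27.5%), against a mean of 12.3% after circular shifts of the peaks, and 28.4% ± 1.22 (n = 3) in the replicates' own lists. Of the 27 lists, 10 were bound more often than other genes and 3 less often at an adjusted p under 0.05 (Fisher's exact test, two-sided). Fat body markers, genes of the insect counterpart of liver and adipose tissue, were bound in 14 of 19 cases (odds ratio 7.42, exact adjusted p = 0.000164), with the strongest peaks at Lpin, Gpdh1, Desat1 and Lsd-2. Without replicate 1, 2 or 3 this odds ratio was 3.92, 4.49 and 3.73, past the threshold each time. Lpin, which encodes a phosphatidate phosphatase, had a relative signal of 5.16 ± 0.846 (n = 3). Genes for bZIP factors were bound in 13 of 19 cases (odds ratio 5.74, exact adjusted p = 0.000905), a call lost with shifted peaks by the log odds ratio (permutation, adjusted p = 0.104) but not by the difference in bound share (0.00450). After Pdp1 and vri, the strongest of these were REPTOR, a target of TORC1 signalling (5.48 ± 1.35, n = 3), and CrebB (4.41 ± 0.762, n = 3). Genes for ribosomal proteins were bound in 56 of 92 cases (odds ratio 4.15, exact adjusted p = 3.14e-10), led by RpL7 at 4.44 ± 0.451 (n = 3), then RpS27, RpS19b and RpS5a, whose summits are all shared with a neighbouring gene, as is that of RpL7. Genes of oxidative phosphorylation were bound in 47 of 83 cases (odds ratio 3.48, exact adjusted p = 3.08e-07), with the highest signals at COX7AL2 (10.6 ± 1.33, n = 3), ATPsynC (7.82 ± 2.26, n = 3), COX6B and ATPsynbeta, of which COX6B and ATPsynbeta share their summits with neighbouring genes.

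Cell death genes were bound in 12 of 19 cases (odds ratio 4.54, exact adjusted p = 0.00362), with Diap1, the caspase inhibitor, at 4.26 ± 0.997 (n = 3), followed by hid, Dcp-1 and Dark. Autophagy genes were bound in 11 of 20 (odds ratio 3.23, exact adjusted p = 0.0228), led by Atg4b, Atg2, Atg17 and Atg18a, whose summits are shared with Hibch, CG12093, Xe7 and ERR. This call was lost without replicate 1 (odds ratio 1.90), without replicate 3 (1.80) and with each peak counted only for its nearest start site (8 of 20, odds ratio 2.42, exact adjusted p = 0.101). Genes of the Dpp pathway, the fly BMP signal, were bound in 15 of 28 (odds ratio 3.06, exact adjusted p = 0.0111), and shn, the zinc-finger effector of Dpp, had 6.19 ± 1.31 (n = 3), ahead of tkv, dlp and sax. The Dpp call was lost with gene length and number of start sites in the logistic model (odds ratio 2.02) and among the stronger 50% of the peaks (2.50). Glutathione transferases were bound in 18 of 35 (odds ratio 2.80, exact adjusted p = 0.00952), with GstE13 at 5.96 ± 1.12 (n = 3) before GstT4, GstE5 and GstD7, a call lost in a narrower window around start sites (odds ratio 1.98). Insulin and growth genes were bound in 13 of 26 (odds ratio 2.65, exact adjusted p = 0.0303), led by S6k, Pi3K21B, Mnt and Akt. Summits of dlp, sax, Dcp-1, Dark, S6k and GstD7 are shared with a neighbouring gene. The exact p-values of these lists are from Fisher's test. When the peaks were shifted along the arms in place of that test, the number of lists that passed depended on the statistic: 14 with the difference in bound share, the same 13 and neuron markers, but 5 with the log odds ratio: ecdysone response, fat body markers (permutation, adjusted p = 0.00899), ribosomal proteins (0.00899), oxidative phosphorylation (0.0337) and chemosensory receptors (0.00899). The fat body difference was not past the threshold among the stronger 50% of the peaks (odds ratio 2.07, exact adjusted p = 0.233). The cell death and insulin lists fell short with each replicate left out, a filter that keeps fewer of the same optimal peaks.

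Chemosensory receptor genes were bound in 5 of 179 cases (odds ratio 0.0747, exact adjusted p = 3.46e-17), among them Ir60b, Ir94h, Gr64a and Or88a. The summits of Ir60b, Gr64a and Or88a are shared with Letm1, CG11594 and CG12402, and 1 of 179 genes stayed bound with each peak counted only for its nearest start site (odds ratio 0.0201). Male reproductive genes were bound in 4 of 65 cases (odds ratio 0.172, exact adjusted p = 0.000108): Sfp26Ad, whose summit is also that of Gpdh1, Mst85C, which shares its summit with Nmdmc and Rel, Acp63F and Mst87F. Genes for Cpr cuticle proteins were bound in 7 of 70 cases (odds ratio 0.292, exact adjusted p = 0.00218), and Cpr62Ba, Cpr65Aw, Cpr51A and Cpr73D had the highest peaks of these, with the Cpr73D summit shared with Ogdh. In the logistic model with gene length and number of start sites neither the male reproductive list (odds ratio 0.322) nor the Cpr list (0.429) passed. Lists that did not differ from other genes by Fisher's exact test after adjustment included the salivary glue and late puff genes (2 of 21), ecdysteroid synthesis (2 of 14), Hox genes (1 of 11), and markers of neurons (3 of 20), muscle (3 of 20) and blood cells (2 of 18). Also not past the threshold were tracheal genes (4 of 15), chitin enzymes (12 of 37), hair and planar polarity genes (9 of 24), heat shock genes (11 of 27), cytochrome P450 genes (23 of 85), the E(spl) complex (6 of 11), and Toll and antimicrobial peptide genes (7 of 28). Their adjusted p-values lay between 0.143 and 1.

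**Figure D2:**
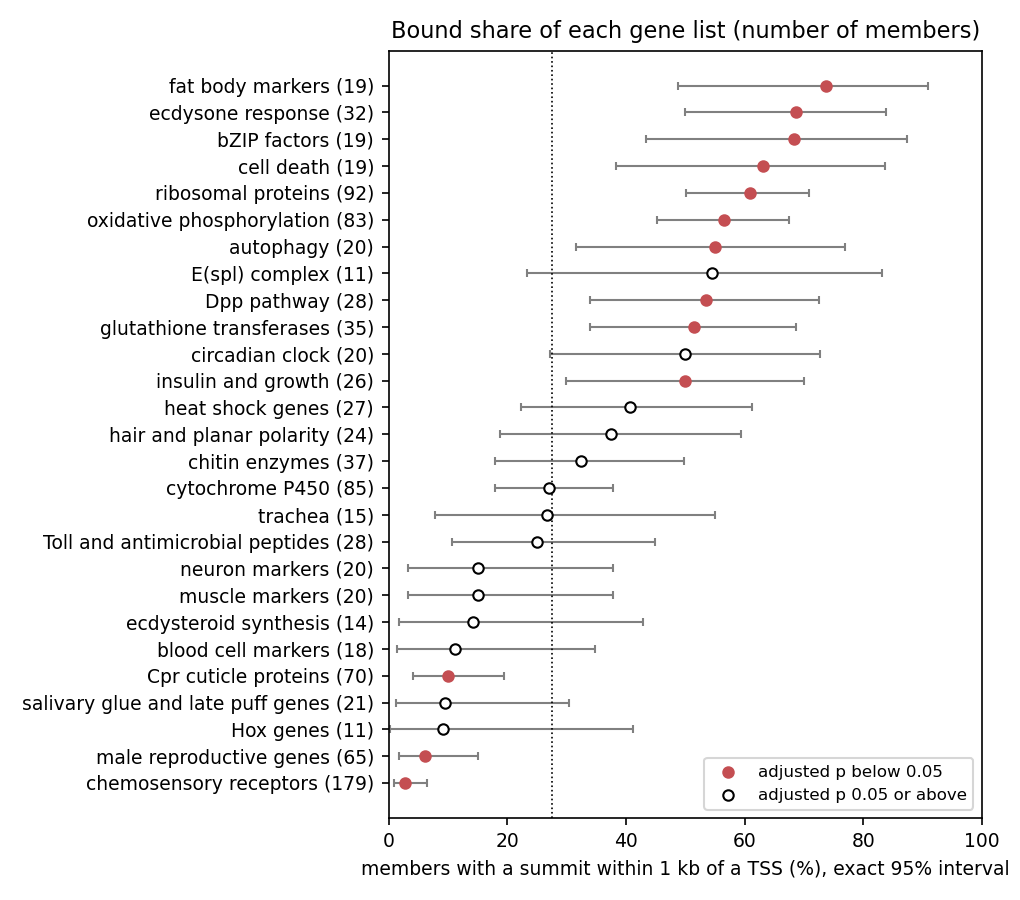
Share of each gene list with an optimal summit within 1 kb of a start site, with its exact 95% binomial interval; the dotted line is the 27.5% of all protein-coding genes, and filled points have an adjusted p under 0.05 by Fisher's exact test. Fat body markers and ecdysone response genes stand highest at 73.7% and 68.8%, chemosensory receptors lowest at 2.79%.

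Summits concentrated at promoters. Of the optimal summits, 4552 (49.1%) lay within 1 kb of a protein-coding start site against 20.3% after 1000 circular shifts, a ratio of 2.42 (two-sided permutation p = 0.001, the smallest the shifts can give). The replicates' own lists gave 50.5% ± 1.24 (n = 3). The median promoter summit lay 32 bp upstream of the nearest start site, with quartiles 195 bp upstream and 110 bp downstream. Of all summits, introns beyond 1 kb of a start site held 36.3% against 36.8% after shifting (permutation p = 0.592), coding exons held 32 summits (0.345%) against 10.8%, 3′ UTRs 1.10% against 3.80%, and intergenic sequence 11.0% against 26.5% (permutation p = 0.001 for the last 3). Of the 4712 summits beyond 1 kb alone, a share computed after the others were seen, introns held 71.4% against 46.2% and intergenic sequence 21.7% against 33.3% (permutation p = 0.001 each). The share within 1 kb of a start site fell from 59.7% in the highest of 10 bins of signal to 40.9 and 43.1% in the lowest ones.

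**Figure D3:**
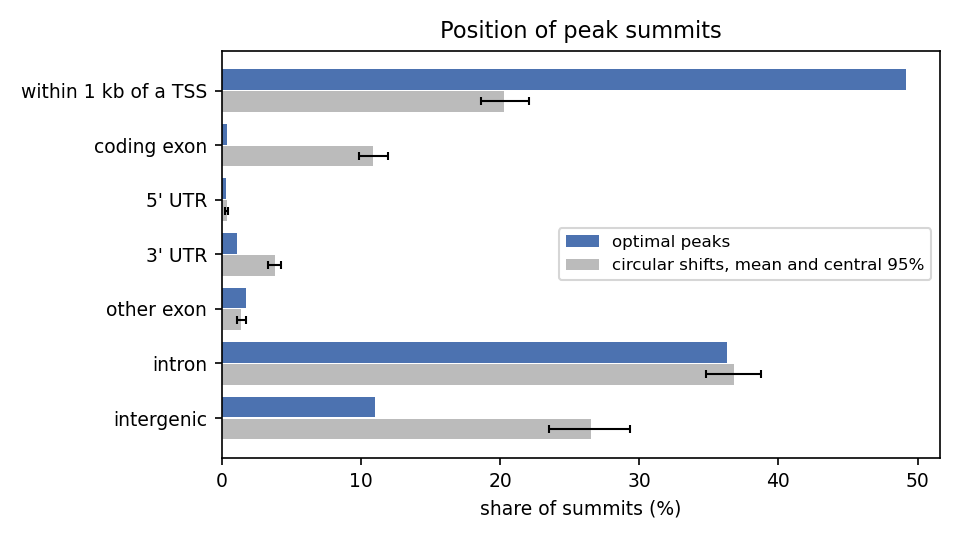
Share of the 9264 optimal summits in each kind of sequence (blue) and after 1000 circular shifts along the chromosome arms (grey, mean with the central 95% of shifts); classes below the promoter class exclude sequence within 1 kb of a protein-coding start site. Promoters hold 49.1% against 20.3%, coding exons 0.345% against 10.8%.

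The VP box TTAYGTAA, the sequence that Vrille and PDP1 bind in the Clk promoter, was found within 50 bp of 217 summits (2.34%, exact 95% interval 2.04 to 2.67%) against 0.831% of windows 400 bp to either side. The ratio was 2.82 (exact McNemar test on 1 flank per peak, two-sided p = 3.58e-15), and the replicates' own lists held it at 2.21% ± 0.234 of summits (n = 3). Among 1120 orders of the same letters the VP box had the highest ratio, where the median order had 1.11. The highest peak near a start site of Clk had no VP box within 50 bp of its summit. The same held for the highest such peak of every other bound gene of the clock and ecdysone lists. The box was at only 2.07% of all summits within 1 kb of a start site, so its lack in this few peaks does not set these genes apart. Related bZIP sequences were raised too: the C/EBP site TTRCGYAA was at 1.96% of summits (ratio 3.83, exact adjusted p = 1.15e-16 over 12 motifs), the looser box TTAYRTAA at 3.38% (ratio 2.31, adjusted p = 2.31e-16) and the cyclic AMP response element TGACGTCA at 0.421% (ratio 2.60, adjusted p = 0.00457). The last of these calls was lost without replicate 1 (ratio 2.46, exact adjusted p = 0.0502), without replicate 3 (2.07, 0.144) and among the stronger 50% of the peaks (2.11, 0.0896). The C/EBP site and the looser box overlap with the VP box. Every VP box is also a looser box, and TTACGTAA, at 61 summits, is both a VP box and a C/EBP site. Part of their excess is therefore that of the VP box. Outside the bZIP family, the DREF site TATCGATA (ratio 2.09, adjusted p = 0.00407), GAGAG (ratio 1.29, adjusted p = 1.79e-11) and CAGCTG (ratio 1.23, adjusted p = 0.00457) passed the same exact test, where CAGCTG fell short without replicate 1 (ratio 1.22, adjusted p = 0.0502) and among the stronger 50% of the peaks (1.24, 0.0832), with fewer peaks and a ratio that hardly moved. The E box CACGTG, through which CLOCK and CYCLE act, was not raised (ratio 0.904, exact adjusted p = 1), nor were the general E box CANNTG, the Zelda site, the AP-1 site or the EcR/USP inverted repeat (ratios 0.804 to 1.18). With the search within 25 bp of the summit, 3 of the 6 raised control motifs stayed past the threshold. The DREF site was among those lost (ratio 1.95, exact McNemar adjusted p = 0.160), with a ratio that moved little but only 0.399% of summits holding it.

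Without a preset motif, 28554 words of 8 bases were compared between summits and both flanks by Fisher's exact test, and 416 were more frequent and 236 less frequent at summits after adjustment. The leading words held the GATA core: ATCTTATC was at 2.34% of summits against 0.691% of flanks (ratio 3.39, exact adjusted p = 4.81e-25), and CTGATAAG and CGATAAGA had ratios of 3.55 and 4.23. Of the 47 tested words with GATAAG on either strand, 36 were among those raised, and 12 were among the 30 raised words with the lowest p; this core was counted after the words were seen. Further down stood bZIP words: TGACGTAA had a ratio of 7.67, TTACGTAA 5.08 and TTACGCAA 4.41. TTATGCAA was at 2.28% of summits against 0.912% of flanks, and the first VP box word stood in place 17. Words of neither kind were mixed with these and came ahead of the VP box words, such as CAACACTG (ratio 4.09), GAGCGAGA (2.52) and CACTGAGA (4.73). With windows of 25 bp and 100 bp the raised words numbered 127 and 907, and the word with the lowest p was ATCTTATC again within 25 bp but CACTGAGA, which has no GATA core, within 100 bp.

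**Figure D4:**
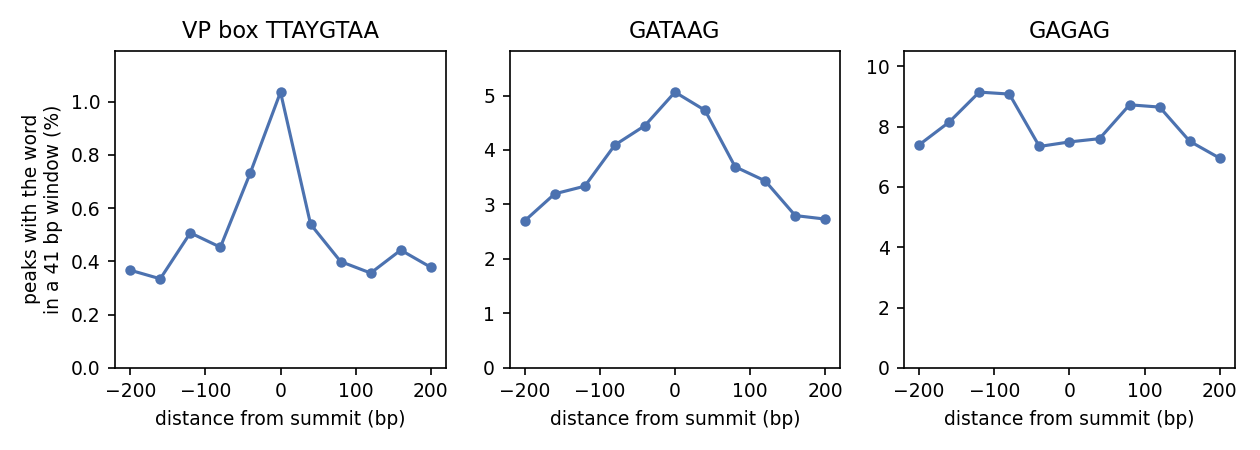
Share of the 9264 optimal peaks with the VP box, GATAAG or GAGAG in windows of 41 bp centred at distances of up to 200 bp from the summit. The VP box and GATAAG are highest at the summit (1.04% and 5.06%), while GAGAG is at 7.49% at the summit and 9.14% at 120 bp to its left.

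Peaks with a VP box had higher signal. In the highest of 10 bins of signal 4.64% had one, against 1.73 to 3.02% in the others, and the mean rank of peaks with a box was higher by 6.06% of the list (permutation test with 100000 resamples, two-sided p = 0.00203). Their median pooled signal was 230 against 196 without the box.

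The replicates named largely the same places. Of the optimal peaks, 89.4% overlapped one of the 9264 highest entries of replicate 1, 83.9% of replicate 2 and 88.1% of replicate 3 (mean 87.1% ± 2.91, n = 3), where shifted peaks gave 4.83%. All 3 replicates held 6531 of them (70.5%, against 2.92% for shifted peaks), and 52 were in none of these lists. The share in all 3 was 42.0% when the overlap had to cover 50% of each peak. Across peaks, which are not independent replicates, the Spearman correlation of signal was 0.718 between replicates 1 and 2, 0.720 between 1 and 3, and 0.620 between 2 and 3. Replicate 2 had the lowest median signal at optimal peaks, 46.8 against 81.4 and 78.5, on a scale not adjusted between libraries. The optimal list was drawn from these same replicates and is not independent of them.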

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

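The counts of words with GATAAG, the tests of that word under the threshold, and the test of extra copies of vri were chosen after the results they bear on had been seen; the other tests of the patterns below were chosen after the patterns but before their own results. Entries of the pooled list that did not pass the IDR threshold, which no comparison above uses, also held the VP box: 1.29% of these 20736 entries had it within 50 bp of the summit, against 0.738% of their flanks (ratio 1.75, exact McNemar test, two-sided p = 1.18e-08). The optimal list in dm3 coordinates holds 10 peaks outside the 6 arms, on sequences named 3LHet, XHet and Uextra, with the strongest at rank 3244.

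Peaks in the gene of the tagged protein ranked 2 and 4 in the genome. Extra copies of the locus in the tagged line would raise all its entries alike. The 5 weakest of the 10 pooled entries within 1 kb of the gene had a median relative signal of 0.350 (range 0.194 to 0.627). They were picked for low signal, and all entries under the IDR threshold lie under the median optimal peak anyway. These values therefore cannot tell added copies from none. Broad signal around the locus was looked for in the entries within 20 kb on either side, beyond the gene and 1 kb around it. Their summed signal stood at percentile 74.9 of all protein-coding genes. The place of the insertion is not known here, so this argues only against broad signal at vri itself, not around an insertion elsewhere. A gain from added copies remains possible, and no input library was analysed here to measure it. No biological explanation was tested, since the samples form 1 group; binding of Vrille at its own gene may be put as a hypothesis.

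The GATA core, rather than the VP box, led the words within 50 bp of summits, though not those within 100 bp: GATAAG was within 50 bp of 12.2% of summits and in 5.36% of flanks. Base composition is argued against, since the median ratio of the 60 orders of these letters was 0.991. GATAAG had the highest, 2.28, but its first place adds no support, because it was picked as the leading core at these same summits. Sharing of peaks with the VP box is argued against too: GATAAG was in 9.68% of peaks with a box and 12.3% without (odds ratio 0.764, interval 0.460 to 1.21, Fisher's exact test p = 0.294). GATAAG was also raised in entries under the threshold, with a ratio of 1.61 (exact McNemar test, p = 3.31e-30). In the same entries the VP box had a ratio of 1.75 and the C/EBP site 1.93. This rise therefore cannot tell accessible sites from weakly bound ones. Accessible sites that attract signal at many strengths remain open. Within the optimal peaks the mean rank of peaks with GATAAG was higher by 0.450% of the list (permutation p = 0.623), whereas the VP box had 6.06%. The difference between these words was not tested, and no biological explanation was tested.

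Genes for ribosomal proteins and oxidative phosphorylation were bound more often than other genes. Peaks that belong to close neighbours are argued against: with each peak counted only for its nearest start site, the odds ratios were 4.57 for ribosomal proteins and 3.76 for oxidative phosphorylation (Fisher's exact test, p = 6.81e-09 for the latter). Pull-down at strongly transcribed promoters without a bZIP site cannot be told apart from sequence-specific binding, because the counts are small: 7 of 137 peaks at these genes (5.11%, exact interval 2.08 to 10.2%) had a VP box or C/EBP site, against 2.55% of their flanks (exact p = 0.0703) and 2.99% of other promoter peaks (Fisher's exact test, p = 0.197). Heat shock genes were not past the threshold (11 of 27). No biological explanation was tested.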

How the results depend on the processing

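The alternatives of this part were set before the data were examined, except that the statistic of the circular shifts of lists was chosen after the results had been seen. The VP box at summits (ratios 2.10 to 4.88), its relation to signal (5.37 to 8.22% of the list), summits near a start site (ratios 1.88 to 3.32) and the ecdysone list (2.74 to 18.9) kept their direction and side of the threshold under each alternative run for them. Among these, the settings without one replicate only filter the same optimal peaks, so they cannot show that a result stands without that replicate. The number of peaks was 9083 in dm3 and 8332 with overlapping peaks merged. It was 6953 to 7405 without one replicate, a filter of the same list that can only lower the number. The share of peaks in all replicates was 42.0% with overlap of 50% of each peak, 57.3% with summits within 100 bp, 97.6% with full lists and 65.1% for the 1000 highest peaks; without one replicate it was 75.1 to 79.9%, where fewer lists had to share a peak. Raised control motifs numbered 3 with windows of 25 bp, and raised words 127 and 907 with 25 and 100 bp. Lists past the threshold were 8 with the stronger 50% of the peaks and 5 with circular shifts of the log odds ratio, but 14 with shifts of the difference in bound share. The values that follow are odds ratios of lists, and the cause of these moves was not tested. Past the threshold only under an alternative were the clock list in the narrower window (3.35), 2 kb (3.02) and gene bodies (2.92), glue genes in 2 kb (0.211), gene bodies (0.205) and peaks of all replicates (0), and hair genes in gene bodies (2.73). Without one replicate glue genes had 0 to 0.163, past the threshold without replicates 1 and 3 but not without replicate 2. In the logistic model Hox genes (0.0654), muscle (0.0895), neuron (0.0656) and blood cell markers (0.168) and the E(spl) complex (5.85) passed. No longer past it with the stronger 50% of the peaks were Dpp (2.50), cell death (1.60), insulin (2.38), fat body (2.07) and autophagy (1.93). With peaks of all replicates these were cell death (2.16), insulin (2.31) and autophagy (1.99). In the logistic model they were Dpp (2.02), insulin (2.27), Cpr (0.429) and male reproductive genes (0.322). With circular shifts of the log odds ratio, where the value is the observed odds ratio over that of shifted peaks, they were Dpp (2.36), bZIP factors (3.50), cell death (4.36), insulin (2.42), Cpr (0.346), male reproductive genes (0.226), autophagy (3.39) and glutathione transferases (3.26). The insulin list also fell short in 2 kb (2.35) and glutathione transferases in the narrower window (1.98). Without one replicate cell death had 2.44 to 2.94, insulin 2.04 to 2.59 and autophagy 1.80 to 3.99; cell death and insulin fell short each time, autophagy without replicates 1 and 3. Reversed were only results not past the threshold in the report. CANNTG had a ratio of 1.01 with the stronger 50% and 0.998 to 1.01 without one replicate, and the EcR/USP repeat had 0.857 with 100 bp and 0.400 with the stronger 50%. Hair genes had 0.777 in the logistic model. Trachea had 1.22 in the narrower window, 1.34 in 2 kb, 2.23 in gene bodies and 0.814 to 1.22 without one replicate. P450 genes had 1.04 in 2 kb, 1.06 in gene bodies, 1.20 in the logistic model, 1.09 with shifts and 1.00 to 1.03 without one replicate. Toll genes had 1.12 in the narrower window, 1.30 in 2 kb, 1.23 with the stronger 50%, 1.23 with peaks of all replicates and 1.09 to 1.17 without one replicate. With summits matched within 100 bp, the signals of 77 named genes moved by less than 1 SD; leaving out a replicate cannot move a mean that far and tests nothing here. Depth is unknown, so what it limits cannot be given. No paired analysis was possible because there is 1 group.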

Other observations

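The motif tests of this part were chosen after the peaks had been seen. None of the 15 highest peaks had a VP box within 50 bp of its summit. So small a set can lack it by chance, since only 4.64% of the highest of 10 bins of signal had one. The highest peak with a VP box, in place 27, lay in an intron of upSET on 3L and held TTACATAA at 14006928 to 14006935 (relative signal 9.80 ± 1.03, n = 3). Next came an intron of tara on 3R, 151 bp from a start site, with TTACATAA at 16242664 to 16242671 (8.39 ± 0.958, n = 3), an intron of Dbct on X with TTATGTAA at 15086358 to 15086365 (8.41 ± 1.28, n = 3), and an intron of Glut4EF on 3R with TTACGTAA at 9928654 to 9928661 (8.17 ± 1.02, n = 3). tara, which encodes a CyclinA regulator that promotes sleep, and Glut4EF, a transcription factor gene, have these summits 151 and 214 bp from a start site. The Pdp1 peak held TTATATAA at 7867638 to 7867645 and TTATGTAA at 7867649 to 7867656, 48 and 59 bp from its summit, so the VP box word lies outside the window searched. The peaks of vri ranked 2 and 4 held no VP box, looser box or C/EBP site over their whole length, and 3 GATAAG words each.

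Within 50 bp of a summit, C/EBP sites came higher in the list than VP boxes, at place 12 against 27. TTACGCAA lay at 9553255 to 9553262 on 2R in the peak of place 12, 5134 bp from CG1888 (relative signal 11.7 ± 1.32, n = 3), and at 19260351 to 19260358 on 3L in the peak of place 18 (11.2 ± 2.11, n = 3). The summit in place 18 lay inside nes and in an exon, whose gene was not recorded. The summit shared by slmb and CG5793, in the 5′ UTR of CG5793, held TTGCGCAA at 21127825 to 21127832 on 3R. Further from the summit, at 128 bp, the ush peak in place 3 held TTGCGCAA at 480924 to 480931 on 2L. Peaks with a C/EBP site had a mean rank higher by 8.08% of the list (permutation test, two-sided p = 2e-04), a relation not planned for this motif.

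Among the 200 highest peaks GAGAG was in 6.5% of windows of 41 bp at the summit, in 20.5% of those centred 120 bp to the left and in 20% of those 120 bp to the right. In the same peaks GATAAG was in 8% of windows at the summit and in 3% and 3.5% of the windows at those distances, and the VP box was in 2.5% at the summit (5 peaks) and 3% at 80 bp to the left (6 peaks).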
